A study of Mus musculus with 6 samples.

How the data were processed

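RNA was measured in 6 samples of KMWT1, a mouse glioma cell line, taken 48 hours after transfection with siRNA. Per the labels, 3 samples (1, 2 and 3) received a control siRNA and 3 (4, 5 and 6) an siRNA pool against YY1. Nothing in the labels says that the samples of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical. No sample number occurs in both groups.

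The authors deposited one table of read counts per gene symbol for each sample. The values are whole numbers with a different total in each sample, and no normalization was applied before deposit as far as the values show. Per the submitters' processing notes, STAR 2.6.1a and edgeR 3.30.0 were used with the mouse genome build mm10. The counting program, the annotation and the strand setting are not given in the sources used here, so reads of overlapping genes on opposite strands may not have been told apart. The tables of 5 samples are marked as combined and that of YY1 siRNA sample 6 is not, and what was combined is not given in the sources used here. Each deposited count table holds 24982 gene symbols and 2 rows that name no gene. Those rows hold the counts assigned to no gene, 7.87% to 11.3% of a sample's counts, and ambiguous counts, 1.01% to 1.15%. They were left out of library sizes and tests. Counts in genes ranged from 15738457 in YY1 siRNA sample 6 to 20644057 in control siRNA sample 1, at which 3 counts equal 0.191 and 0.145 CPM, the usual unit of counts scaled by library size.

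The main test was the quasi-likelihood F test of edgeR 4.0.16 (R 4.3.3), two-sided, on the deposited counts, with filterByExpr, TMM normalization and robust estimation of dispersion. It kept 12148 genes. P-values were adjusted by the method of Benjamini and Hochberg with a threshold of 0.05. CPM values are TMM-normalised and given as mean ± SD (n = 3). Before the data were examined, 36 gene lists were fixed, and 33 of them had at least 5 genes tested. Each was tested with camera (limma 3.58.1), with a preset correlation between genes of 0.01, and adjusted over the lists. Camera with an estimated correlation and fry were alternatives. A list's level in a library is the median of its genes' log2 CPM, each relative to its mean over the 6 libraries.

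Genes named in the text follow a rule fixed before the data were examined. It takes Yy1, the genes with the largest changes among those that passed, up to 4 members of each described list and the 4 genes with the smallest adjusted p. Members of a list in which none passed are given only as values. Vim, Sox2, Col3a1, Gja1, Nefl, Nefm, Flt1, Yy2, Zfp42, Malat1 and Kcnq1ot1 are named outside this rule, chosen after the data were seen, and other genes outside it are marked where they are named.

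Alternatives to the main settings were RLE size factors, library size alone, no filter on low counts, a filter of at least 1 CPM in 3 samples, counts thinned to the smallest library, and offsets for transcript length and GC content (mgcv 1.9.3). DESeq2 1.42.0, limma-voom, edgeR without robust estimation, glmTreat against 1.5-fold and leaving out each sample in turn were also run. Added after the data were seen were limma-voom with sample weights and a fit with the share of counts in no gene as a covariate. Gene models came from GENCODE M21 on mm10, to which 98.0% of the symbols matched.

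A test of the YY1 motif within 100 bp of transcription starts had been planned for genes past the adjusted threshold. No genome sequence was used here and 1 gene passed. The motif AANATGGCG was therefore searched on both strands of the first 100 bases of annotated transcripts, for all tested genes, and genes with an unadjusted p under 0.05 took the place of changed genes. This choice was made after the data were seen. The first 100 bases leave out sequence upstream of the start and can hold the start codon, whose context resembles the motif.

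The steps were tested on simulated counts for the 12148 genes, with means, depths and dispersions of the real libraries and 200 genes changed. The main test recovered 9.0% of genes changed by 1.25-fold, 76.5% at 1.5-fold and 92.5% at 2-fold, with 7, 10 and 11 false calls. In a first simulation of the list test, 1 unshifted list of 40 genes gave an unadjusted p of 0.0117 with the preset correlation and 0.195 with an estimated one. A larger simulation was then added, in which both forms called 50 of 50 lists shifted by 1.2-fold and 0 of 50 unshifted lists. Simulated genes are independent, unlike real ones.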

Results

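The series asked what lowering YY1, a zinc finger transcription factor that can activate or repress genes, does to gene expression in KMWT1 glioma cells. RNA-seq counts were compared between 3 control siRNA samples and 3 YY1 siRNA samples, each taken 48 hours after transfection. Control siRNA samples 1, 2 and 3 held 20644057, 19209772 and 18680762 counts in genes, and YY1 siRNA samples 4, 5 and 6 held 19210104, 18644522 and 15738457. No pair of samples within a group agreed within sampling noise (chi-square per degree of freedom 3.13 to 32.5), so no pair looked like repeated copies of 1 library. The first principal component held 44.2% of the variance and set YY1 siRNA sample 6 apart, the sample with the fewest counts and the one whose table, unlike the other 5, is not marked as combined. The second component, with 18.7%, set YY1 siRNA sample 4 apart.

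The cells expressed part of the glioma stem and progenitor markers, with 10 of 20 at 10 CPM or more and 8 under 1 CPM, and part of the fibroblast and pericyte markers, with 7 of 13 at 10 CPM or more and 3 under 1 CPM. Vim, an intermediate filament gene, was the most abundant transcript at 11191 ± 813 CPM in control siRNA samples and 10502 ± 1228 CPM in YY1 siRNA samples (SD, n = 3). The neural stem cell factor Sox2 stood at 671 ± 43.9 and 675 ± 72.5 CPM, and the hyaluronan receptor gene Cd44 at 994 ± 24.6 and 938 ± 75.1 CPM. Among fibroblast markers, the collagen gene Col3a1 stood at 875 ± 64.8 and 803 ± 114 CPM. Of 15 astrocyte markers, 5 stood at 10 CPM or more and 7 under 1 CPM, with the gap junction gene Gja1 at 619 ± 11.7 and 618 ± 34.0 CPM. Of the markers of other cell types, 10 of 15 for neurons, 10 of 15 for the oligodendrocyte lineage, 13 of 16 for microglia and macrophages, and 8 of 11 for endothelium stayed under 1 CPM. Among those above it were the neurofilament genes Nefl (316 ± 14.7 and 307 ± 25.4 CPM) and Nefm (193 ± 16.2 and 195 ± 13.5 CPM) and the endothelial receptor gene Flt1 (124 ± 10.9 and 122 ± 13.9 CPM). No member of the 7 cell type lists passed the edgeR test over all genes, 5 of 49 had an unadjusted p under 0.05, and DESeq2 called 1, Anpep (adjusted p 0.0229). Adjusted over the list alone, 3 of the 10 tested fibroblast and pericyte markers passed: Anpep was lower (36.1 ± 5.63 against 24.6 ± 1.61 CPM), while Dcn (9.68 ± 0.759 against 11.9 ± 0.751 CPM) and Rgs5 (1.22 ± 0.199 against 1.94 ± 0.169 CPM) were higher. Among 3 tested microglia and macrophage markers, Tmem119 passed in the same way (49.9 ± 2.12 against 42.3 ± 2.90 CPM).

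Yy1 fell with YY1 siRNA. The gene lies on the plus strand of chromosome 12 from 108792973 to 108820148 (mm10, ENSMUSG00000021264.12), and the annotation places no other gene over it. Its level was 127 ± 0.826 CPM in control siRNA samples and 79.2 ± 1.86 CPM in YY1 siRNA samples (SD, n = 3), which is 62.3% of control (95% interval 56.5% to 68.6%). The log2 fold change was -0.68 (SE 0.064, edgeR adjusted p 0.00154). All 3 YY1 siRNA samples lay below all 3 control samples. The related gene Yy2 had 115 to 167 counts per library, and Zfp42, the other relative in mouse, had 0.

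**Figure D1:**
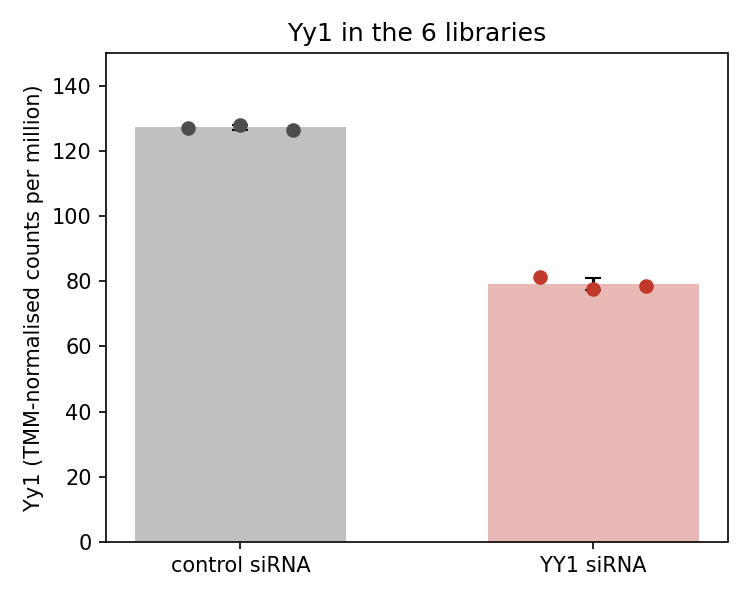
Yy1 in TMM-normalised CPM (vertical axis) in control siRNA and YY1 siRNA samples. Bars are means, error bars are SD over 3 samples and points are single samples; the 3 control samples lie near 127 CPM and the 3 YY1 siRNA samples between 77.6 and 81.2 CPM.

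No other gene passed with edgeR at the main settings, while alternative settings and tools gave 1 to 83 changed genes. Of 12148 genes tested with edgeR, 1 had an adjusted p under 0.05, Yy1 itself, and 0 had such a p with a change of at least 2-fold. At an unadjusted p under 0.05 there were 1316 genes, 653 higher and 663 lower, against 607 expected by chance. The 607 takes no account of correlated genes or of structure among the samples. Other splits of the 6 samples into 3 and 3 gave 66 to 1936 such genes, so the excess cannot be credited to the siRNA. DESeq2 called 19 genes, 14 lower and 5 higher, and limma-voom called 1. The next genes by edgeR's adjusted p were Mgarp, a mitochondrial protein gene (63.2 ± 1.90 CPM in control and 44.4 ± 2.86 CPM in YY1 siRNA samples, adjusted p 0.0713), Sprr2k (6.38 ± 0.713 and 11.1 ± 1.15 CPM, adjusted p 0.0957) and Lmln (7.26 ± 0.540 and 4.16 ± 0.355 CPM, adjusted p 0.0957). DESeq2 called these 3 genes (adjusted p 0.000855, 0.00505 and 0.0386), as did edgeR with library size alone and without a filter on low counts, and limma-voom with sample weights, which was added after the data were seen. Lmln shares its locus with Gm22231 and Mir1947 on the same strand and Gm17106 on the other, so its counts are uncertain. The 95% interval lay within 2-fold in either direction for 95.9% of tested genes and within 1.5-fold for 82.2%. Leaving out YY1 siRNA sample 4 raised the count of changed genes to 41, 24 higher and 17 lower.

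Among YY1 partners and Polycomb genes, 0 of 14 tested members passed over all genes with edgeR and 0 with DESeq2, while 3 had an unadjusted p under 0.05. Adjusted over the list alone, L3mbtl2, a Polycomb-related gene, was lower (16.7 ± 1.95 CPM in control, 11.8 ± 0.115 CPM in YY1 siRNA samples) and Cbx7 was higher (13.5 ± 1.06 and 17.1 ± 0.556 CPM). The list as a whole had a median log2 fold change of 0.035 (camera adjusted p 0.998). Imprinted genes gave 0 of 13 tested members past the threshold with edgeR, 0 with DESeq2 and 1 at an unadjusted p under 0.05, with a median of -0.11 (camera adjusted p 0.509).

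Of the 33 gene lists tested, 6 lay higher on average in YY1 siRNA samples and 3 lower, with camera at a preset correlation. Of 40 mitosis genes, 40 had a fitted change above 0 (median log2 fold change 0.16, adjusted p 4.93e-10), with Kif11 at 69.6 ± 9.34 and 89.7 ± 10.9 CPM and Birc5 at 47.1 ± 6.09 and 58.3 ± 5.31 CPM. With an estimated correlation the call was lost (adjusted p 0.827), as were those of the other 5 lists here (adjusted p 0.827 for each). Of 43 DNA replication genes, 36 had a fitted change above 0 (median 0.13, adjusted p 1.92e-06). Cytosolic ribosomal protein genes (median 0.22, 66 of 68 above 0, adjusted p 4.93e-10), nuclear-encoded oxidative phosphorylation genes (0.18, 60 of 75, adjusted p 1.92e-06), mitochondrial ribosomal protein genes (0.098, 57 of 72, adjusted p 0.00018) and cholesterol synthesis genes (0.074, 20 of 25, adjusted p 0.00184) lay higher too. The samples of the groups overlapped in each of the 6 lists (exact permutation p of the levels 0.3 to 0.6, two-sided, smallest possible 0.1). Control siRNA sample 3 had the highest DNA replication level, 0.0897, against 0.0794, 0.0221 and 0.0836 in YY1 siRNA samples 4, 5 and 6. Its mitosis level, 0.0926, lay above YY1 siRNA samples 5 (0.00722) and 6 (0.0912). No member of these 6 lists passed over all genes with edgeR, and 50 of 323 had an unadjusted p under 0.05. Of the 68 cytosolic ribosomal protein genes, 0 had such a p. Among the 50, 2 mitochondrial ribosomal genes and 1 oxidative phosphorylation gene were lower. Of the 323, DESeq2 called 1, Sdha (adjusted p 0.0229). Adjusted over the list alone, Sdha, a subunit of succinate dehydrogenase, was lower (213 ± 8.39 and 162 ± 14.0 CPM), against the direction of its list, and Pmvk, a kinase of the mevalonate pathway, was higher (54.1 ± 1.06 and 67.9 ± 0.646 CPM). Without YY1 siRNA sample 6, the medians were 0.035 for cytosolic ribosomal proteins, 0.023 for oxidative phosphorylation and 0.015 for mitochondrial ribosomal proteins, and these 3 lists no longer passed. With offsets for transcript length and GC content, the oxidative phosphorylation (0.080) and mitochondrial ribosomal (0.045) calls were lost. Cholesterol synthesis was lost without control siRNA sample 3 (0.014) and without YY1 siRNA sample 4 (0.059). The highest medians with a sample left out were 0.32 for cytosolic ribosomal proteins and 0.26 for oxidative phosphorylation. They were 0.18 for mitochondrial ribosomal proteins and 0.14 for cholesterol synthesis. The mitosis and DNA replication medians were 0.10 and 0.083 without control siRNA sample 1, and the mitosis median was 0.24 without control siRNA sample 3. At the preset correlation, the mitosis and DNA replication calls held without each sample in turn (highest camera adjusted p 0.000308 and 0.00143).

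Interferon response genes, which antiviral signalling induces, lay lower with camera at the preset correlation. Of 43 tested, 39 had a fitted change below 0 (median -0.18, adjusted p 2.27e-10). With an estimated correlation the call was lost (adjusted p 0.827). None of the 43 passed over all genes with edgeR and 14 had an unadjusted p under 0.05, while DESeq2 called Oas3 (adjusted p 0.0229) and Ifit3b (adjusted p 0.0443). Adjusted over the list alone, 3 passed with edgeR: Oas3 (92.6 ± 13.6 CPM in control and 66.2 ± 3.57 CPM in YY1 siRNA samples), Ifit3b (21.1 ± 4.66 and 13.6 ± 0.980 CPM) and Irf7 (150 ± 19.1 and 117 ± 7.93 CPM). MHC class I genes (median -0.098, 15 of 17 below 0, adjusted p 0.0362) and MYC targets (-0.077, 25 of 38, adjusted p 0.0376) lay lower as well. In both of these lists the levels of all 3 YY1 siRNA samples lay below those of all 3 control siRNA samples. The exact permutation p was 0.1 for each, two-sided, the smallest that 3 against 3 allows. Neither of these 2 calls held with an estimated correlation (adjusted p 0.827 for each). Neither held with counts thinned to the smallest library (medians -0.080 and -0.078). With length and GC offsets the MYC call was lost (-0.050). Fry called 0 of the 33 lists. Control siRNA sample 1 had the highest interferon level at 0.293 and YY1 siRNA sample 4 the lowest at -0.246, while YY1 siRNA sample 6, at 0.0060, lay above control siRNA sample 2 at -0.0280. The interferon median was -0.073 without control siRNA sample 1. At the preset correlation, the interferon call held without each sample in turn (highest camera adjusted p 0.00143). The MHC class I call was lost without control siRNA sample 1 (-0.035), YY1 siRNA sample 4 (-0.095) or YY1 siRNA sample 5 (-0.077), and the MYC call without control siRNA sample 3 (-0.065) or any of YY1 siRNA samples 4, 5 and 6 (-0.068, -0.069 and -0.047).

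**Figure D2:**
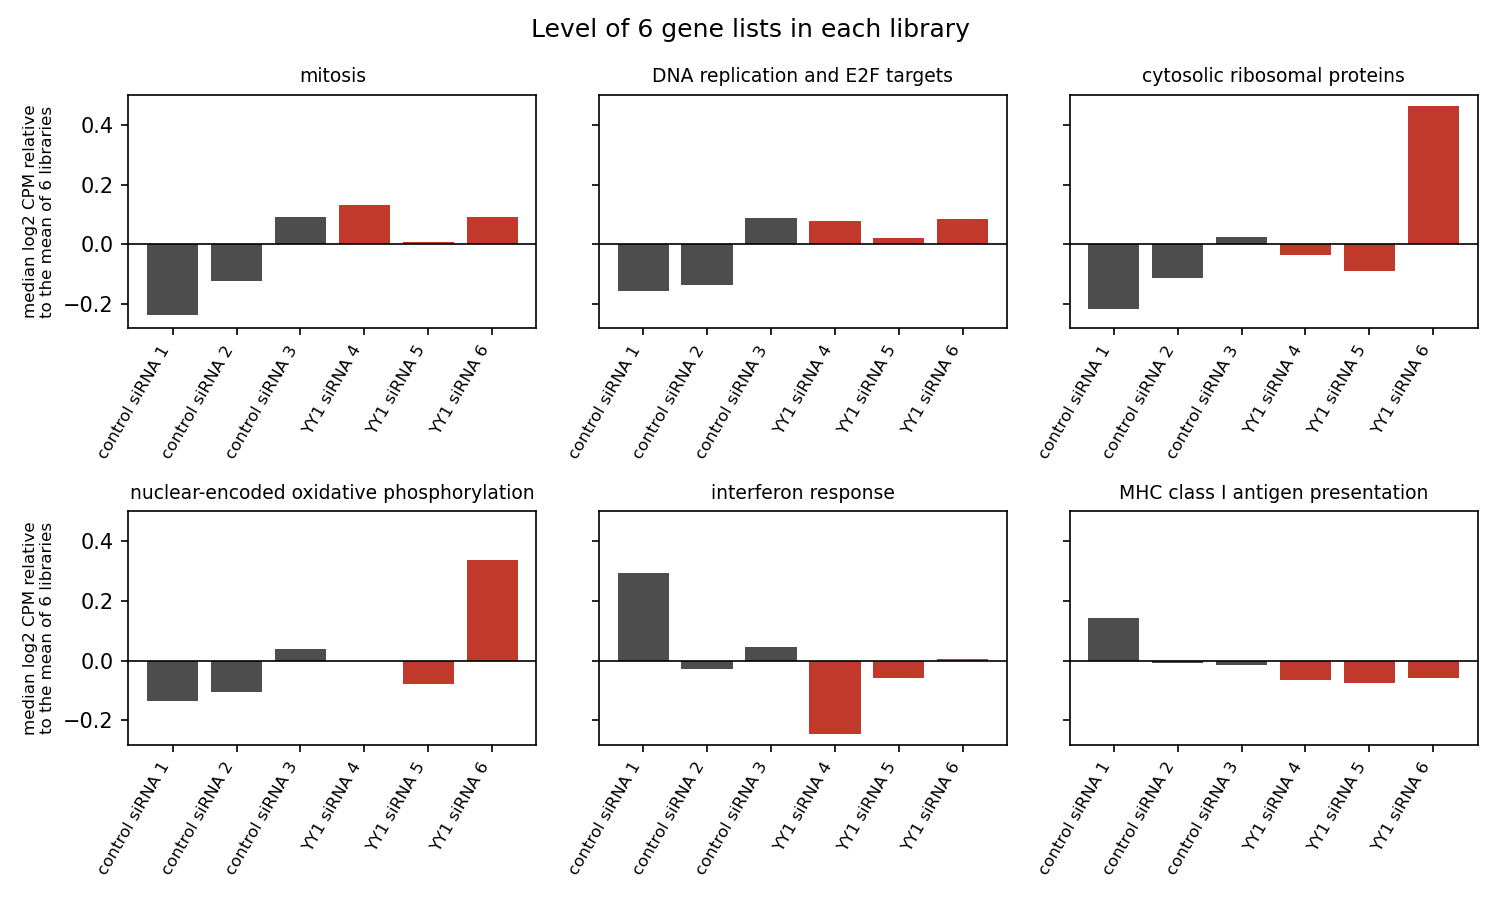
Level of 6 gene lists in each library, as the median log2 CPM of the genes relative to their mean over the 6 libraries (vertical axis); gray bars are control siRNA and red bars YY1 siRNA samples. The cytosolic ribosomal level is 0.466 in YY1 siRNA sample 6 and below 0.03 in the other 5 samples.

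Genes with the YY1 motif near the start of a transcript had more small p-values than other genes, in both directions. Of 712 tested genes with AANATGGCG in the first 100 bases, 138 (19.4%) had an unadjusted p under 0.05, against 1168 of 11346 genes without it (10.3%, odds ratio 2.09, 95% interval 1.71 to 2.55). The motif was present in 11.6% of genes lower at that p, 9.55% of genes higher and 5.34% of the rest (Fisher's exact test, two-sided, adjusted over both comparisons, p 3.92e-09 and 2.90e-05). The motif genes did not move one way: their median log2 fold change differed from that of other genes by 0.0024 (95% interval -0.011 to 0.014). The interval and these p-values treat genes as independent, which they are not, and the motif search and its gene set were chosen after the data were seen. Among the motif-bearing genes, Hcfc1, named after its values were seen, had a log2 fold change of 0.38 (SE 0.0801, edgeR adjusted p 0.147).

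**Figure D3:**
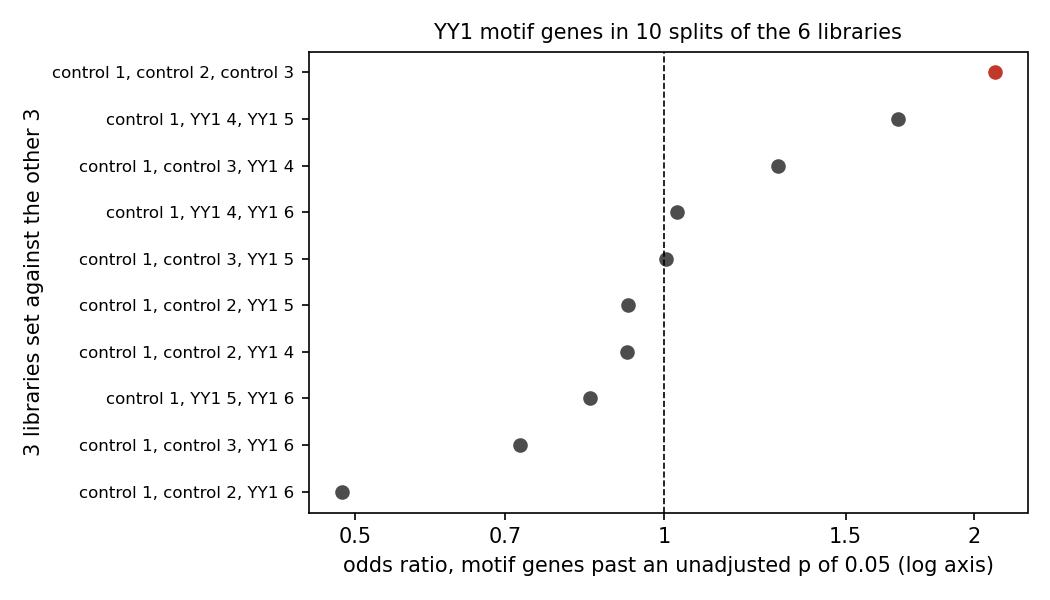
Odds ratio (horizontal log axis) for genes with the YY1 motif to have an unadjusted p under 0.05, for each of the 10 splits of the 6 libraries into 3 and 3. Red marks control against YY1 siRNA samples, at 2.10, and gray the other splits, which lie between 0.486 and 1.69.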

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

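Both tests of the pattern described here were chosen after the result was seen.

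The share of counts assigned to no gene, which the comparisons do not use, was 10.7% in YY1 siRNA sample 5 and 11.3% in YY1 siRNA sample 6. Both lie above the control siRNA samples, at 7.99%, 8.64% and 9.03%, while YY1 siRNA sample 4 had 7.87%. Samples 5 and 6 are also those in which 24 genes were higher once sample 4 was left out, with a median log2 fold change of 0.51. Among them were Tet2 (0.61), Ogt (0.50) and Mdm4 (0.43), named after their values were seen.

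In YY1 siRNA sample 4, where Yy1 was lowered to 81.2 CPM, the median log2 difference of these 24 genes from the control mean was -0.026 (bootstrap SE over genes 0.021). There 37.5% of them kept their sign, below the 81.3% that shared controls alone gave in simulations, and the ratio of this median to that without sample 4 was -0.051 against a simulated 0.457 (SD 0.132). The genes were chosen with that 1 sample left out, and the simulations do not copy the choice of the sample, so the YY1 knockdown stays open as their cause. A candidate explanation is more unspliced or nuclear RNA in samples 5 and 6. The mean log2 level of 6 nuclear-retained noncoding RNAs, among them Malat1 and Kcnq1ot1, was higher in each of these samples than in any of the other 4, by at least 0.263 (SE over the 6 RNAs 0.086). That pattern was partly known when the RNAs were listed, and whether the RNA or its handling differed was not tested. The 17 genes lower without sample 4, Yy1 among them, were all lower in sample 4 too, with a median of -0.28. This is 0.546 of their median without that sample. Shared controls alone gave a ratio of 0.376 (SD 0.112) and the same sign in 80.4% of simulated cases, so part of this agreement may come from them.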

How the results depend on the processing

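Limma-voom with sample weights, the no-gene covariate and every motif setting were chosen after the data were seen. Without the filter on low counts, edgeR also called Oas3, Ifit3b, Irf7, Sdha, Pmvk, L3mbtl2, Anpep, Ckap2, Trp53inp1 and Hmox1 over all genes (adjusted p 0.00263 to 0.0339). No paired analysis was possible because no sample number occurs in both groups. Yy1 kept its direction and passed under all 11 alternatives (log2 fold change -0.71 to -0.62) and without each sample in turn (-0.70 to -0.67, highest edgeR adjusted p 0.0439). The number of changed genes was 7 with library size alone (3 higher, 4 lower), 83 without a filter on low counts (28 and 55), 11 with length and GC offsets (2 and 9), 19 with DESeq2 (5 and 14) and 22 with sample weights (6 and 16). It was 1 to 41 without each sample in turn: 41 without YY1 siRNA sample 4, 3 without YY1 siRNA sample 6 and 2 without control siRNA sample 3. Genes changed at least 2-fold numbered 1 with library size alone, 4 without the filter, 1 with DESeq2, 3 with sample weights, and 0 to 1 without each sample, with the 1 found without YY1 siRNA sample 4. The cause of these differences was not tested. Changed gene lists, 9 in the main test, fell to 0 with an estimated correlation and 0 with fry (smallest adjusted p 0.827 and 0.0549), and numbered 5 to 9 without each sample, with 5 without YY1 siRNA sample 6. They numbered 6 with length and GC offsets, 7 with thinned counts, and 11 without the filter and without genes shared between lists. The motif's median difference was -0.0031 with AANATGG. The odds ratio of motif genes lay between 1.33 (AANATGG) and 3.39 (DESeq2), and between 1.73 and 2.57 without each sample. The DESeq2 value also takes in genes with few counts that the main test had filtered out, so the gene sets are unlike. The planned motif test around transcription starts and its alternatives were not run as written. With this depth and spread, the smallest simulated change was recovered in 9.0% of genes, so changes of that size were mostly not detectable.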

Other observations

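The tests of motif genes past an unadjusted p, and the splits for changed genes and for genes changed at least 2-fold, were chosen after the results were seen. The test of motif genes moving together was added after the data were seen, but before its own result. The camera tests of the gene lists were planned before the data were examined. The tests of the ribosomal, oxidative phosphorylation and interferon patterns name directions and a sample already seen, and were set before their own values. The splits for gene lists were set before their result was seen. Predictions for a mitosis and DNA replication pattern were written and then dropped untested.

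Genes of the p53 response gave the smallest fry adjusted p of the 33 lists, 0.0549. Of the tested members, 14 had a fitted change above 0 and 13 below. The list's levels were -0.028, -0.014 and -0.014 in control siRNA samples 1, 2 and 3. They were higher, at 0.016, 0.0047 and 0.024, in YY1 siRNA samples 4, 5 and 6. The exact permutation p was 0.1, two-sided, the smallest that 3 against 3 allows. The median log2 fold change of the p53 genes was 0.015 (camera adjusted p 0.155). None of 27 tested members passed over all genes with edgeR or DESeq2, and 6 had an unadjusted p under 0.05, all 6 higher. With edgeR, 3 passed when adjusted over the list alone: Ckap2 (45.2 ± 4.81 CPM in control and 59.1 ± 4.28 CPM in YY1 siRNA samples), Trp53inp1 (32.3 ± 2.04 and 42.1 ± 4.79 CPM) and Btg2 (11.0 ± 0.945 and 14.6 ± 1.17 CPM). Of the Notch and Hedgehog list, Hes1 and Notch3 passed in that way, both lower, with log2 fold changes of -0.37 and -0.48. Hmox1, of the immediate early and heat shock list, was lower by the same count (-0.41), and DESeq2 called it over all genes (adjusted p 0.0411). These genes fall outside the rule for named genes. The 24 lists not called by camera had adjusted p-values from 0.078 to 0.998. No mitochondrially encoded transcript is among the symbols analysed here.

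Chance was tested with the 10 splits of the 6 samples into 3 and 3, too few for a share under 0.05. The counts of splits here include the real one. For changed genes, only the real split of the 10 reached its count (1, highest other 0). For genes changed at least 2-fold all 10 did (0, highest other 0), which tests nothing since the real count was 0. For changed gene lists, 5 of the 10 splits, the real one among them, gave at least 9, and the highest other gave 15. That split set control siRNA samples 1 and 2 with YY1 siRNA sample 4. It also had 1936 genes at an unadjusted p under 0.05, against 1316, which points to a structure of the samples other than the siRNA. The share of counts in no gene was 7.99%, 8.64% and 7.87% in those samples. It was 9.03%, 10.7% and 11.3% in control siRNA sample 3 and YY1 siRNA samples 5 and 6. Mean levels of the nuclear-retained RNAs were also lower in the former (-0.26, -0.095 and -0.38) than in the latter (0.038, 0.30 and 0.40). Whether either underlies the split was not tested.

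The ribosomal protein and oxidative phosphorylation lists together had a median log2 fold change of 0.18 over 215 genes. A single library may account for it: without YY1 siRNA sample 6 the median was 0.024 (bootstrap SE 0.0060). That sample has the fewest counts and its table is not marked as combined, unlike those of the other 5, and whether this bears on it was not tested. Offsets for transcript length and GC content left 0.085 (SE 0.012), which removes part of the value and leaves part, so a trend on length and GC content stays open. Both SEs resample genes, which are not independent, so they do not measure the spread between samples. The knockdown itself cannot be told apart from sample structure, since the exact permutation p was 0.4, two-sided, and 3 against 3 allows none under 0.1. For interferon genes the median log2 fold change was -0.25 without YY1 siRNA sample 6 and -0.18 with length and GC offsets. It was -0.073 without control siRNA sample 1, against -0.18 with all 6 samples, so this pattern leans on that sample. The exact permutation p of the interferon levels was 0.2.

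A hypothesis is that lowering Yy1 to 62.3% of its control level moved many motif-bearing genes by small amounts, some up and some down. For 1 shared direction, camera with an estimated correlation gave a p of 0.286 for the 712 motif genes, which detects no shift and excludes none. The median difference from other genes, 0.0024 (95% interval -0.011 to 0.014, genes taken as independent), speaks against a larger shared shift. Neither value tests changes in mixed directions. For a change in either direction, 3 of 100 shuffled motifs gave an odds ratio as large as 2.09, though those motifs occurred in only 8 to 203 genes. Adjusting for expression, GC content and length left an odds ratio of 2.14 (95% interval 1.76 to 2.61). Of 4 other promoter motifs, ETS in 1162 genes gave 0.867, SP in 4528 genes 0.737, CRE in 100 genes 0.341 and NRF1 in 63 genes 1.37 (95% interval 0.595 to 2.82), an interval that overlaps that of the YY1 motif, so other promoter elements stay open. The real split had the highest odds ratio, 1 of 10 splits, with the next at 1.69, and 10 splits cannot give a share under 0.05, so sample structure stays open and the pattern is no more than a hypothesis found and tested on the same data.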
